A study of Mus musculus with 2 samples.

How the data were processed

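Total nuclear RNA of F121-6 hybrid ES cells was sequenced with strand-specific libraries as 100 bp paired-end reads, per the labels' protocols, which also say that earlier libraries were sequenced again and merged with the earlier reads. Alignment used Bowtie2 and the genome build mm10, per the submitters' processing notes, which give no version. The program that counted reads, the set of SNPs that told the alleles apart, the gene annotation and the use of strand are not given in the sources used here. The processed data were 1 table with 48550 rows, each with a window of 5000 bp centred on a gene's start, a name, a strand, a length and 4 value columns, a 129 and a cas column for each of 2 libraries. Each column was assigned to its sample by the name in the sample's description.

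The deposited values are RPKM, although per the file headers the columns are called counts. The products of value and row length in kb summed to nearly the same total in every column (999994.2, 999966.7, 999996.2 and 999972.2), and each such product was a whole multiple of 1 step per column. With a tolerance of 0.01 read, 100.0% of values came out as whole reads, which gave 15300476 and 13223268 reads for 129 and cas in library 1, and 17006241 and 14396524 in library 2. The deposited lengths do not belong to the genes they stand beside. They were within 2 bp of the annotated span for 67 rows, their log lengths had a Pearson r of -0.02 with the annotated spans, and the recovered reads followed the annotated spans (0.48 on log scales) and not the deposited lengths (0.00). The RPKM of different genes therefore cannot be compared, whereas the ratio of alleles within a gene is unaffected, because the length is the same in both columns. Rows were matched by name, chromosome and strand to GENCODE mouse release M21 on the same build, for 46410 rows (95.6%), of which 83.4% had a window centre within 2 bp of the annotated start.

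The design fixed before the data were examined assumed counts and a quasi-likelihood count model. Because the deposited unit was RPKM, limma 3.58.1 in R 4.3.3 was used in its place, on log2 of the recovered reads, scaled to CPM, plus a pseudocount of 0.1, with trended variances, library as a block and allele as the tested term. Fold changes on this scale understate the change of genes with few reads. The block was used since both allele columns of a library come from the same RNA. Columns were scaled by trimmed means of M values (TMM), computed in the same R code. Genes needed at least 20 allele reads in each library, and 1570 rows on the Y chromosome were left out, as the cells are female by the labels. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The prior degrees of freedom were infinite, so that genes of like abundance shared 1 spread. On simulated data for 15396 genes, the same code recovered 67.2% of 67 changes of 1.5-fold, 94.0% of 67 of 2-fold and 100% of 65 of 4-fold. It made 5 false calls (2.8% of calls). The simulation changed 200 genes and gave every gene the same dispersion of 0.003, estimated from genes with many reads. A spread shared between genes thus held by construction, and the share of false calls need not hold for the real data.

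Gene lists, 17 in number and drawn from textbook knowledge, were fixed before the data were examined. They covered maternally and paternally expressed imprinted genes, the X inactivation centre, genes escaping X inactivation, naive pluripotency, formative and primed states, the 2-cell-like state, fibroblast feeders, primitive endoderm, trophoblast, germ layers, replication, genome organisation, Polycomb and DNA methylation, nuclear long noncoding RNAs, histocompatibility and interferon genes, and glycolysis and respiration. A list's median was placed among the medians of 10000 random lists of the same size, with a two-sided p. Random lists were drawn with replacement from all tested genes, matched in 10 bins of the mean log2 value over the 4 columns. Below, they are called matched on reads, and the resampling a permutation test over genes. A gene with reads mostly from 1 allele can fall in a lower bin than an even gene with as many reads. A list's share of called genes was compared with other tested genes by Fisher's exact test (two-sided), and both p-values were adjusted over the lists by Benjamini-Hochberg. The same resampling served for chromosomes, drawing from the other autosomes. Named genes followed a fixed rule. They were the 10 called genes with the largest ratio in each direction, with at least 100 reads and the same direction in each library, without genes whose symbols are of the types for predicted genes, microRNAs (Mir), small nucleolar RNAs (Snor) and pseudogenes (-ps). To these were added the called members of the imprinted, X inactivation and escape lists with up to 4 uncalled ones of highest count, and in each other list the 4 of highest count with up to 2 further called genes of largest ratio. The rule named 135 genes, of which 1 is not reported here.

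The total reads per column and a median of 383 and 461 reads per tested gene and library set the precision. Pooled shares have exact 95% binomial intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. The reads of the libraries differed by more than sampling noise (chi-square per degree of freedom 28.0), so they were not 1 library deposited again. Of the tested genes, 3359 overlap another gene on the same strand and 6453 on the opposite strand. Because the use of strand in counting is not stated, reads of such genes cannot be told apart with certainty.

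Other settings fixed before the data were examined were median-of-ratios size factors, 1 shared library size for both alleles, TMM on autosomal genes, minimums of 10 and 100 reads and no filter, no block, an exact binomial test within each library, leaving out predicted, pseudogene and ribosomal protein symbols, and leaving out each library. Chosen after seeing the data were pseudocounts of 0.02 and 0.5, voom weights, scaling by the deposited column totals, limma's treat against 1.5-fold, protein-coding genes only, and leaving out chromosome 10 or chromosomes 10 and 17. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.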

Results

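Allele-specific nuclear RNA was measured in F121-6 cells, a female mouse embryonic stem (ES) cell line from a hybrid cross that carries 1 set of chromosomes of the 129 strain and 1 set from *Mus musculus castaneus* (cas). The cells were cultured on a layer of mitotically inactivated mouse embryonic fibroblasts (MEFs). Nuclear RNA includes unspliced and unstable transcripts as well as mature messages. The samples form 1 group of 2 libraries, and in each library the reads of every gene were split by the allele they came from. Library 1 held 28523744 allele-assigned reads, 53.6% of them from the 129 allele, and library 2 held 31402765, 54.2% from 129. Of 48550 table rows, 15509 genes had at least 20 allele reads in each library and were tested, with a median of 383 reads per gene in library 1 and 461 in library 2. The study's design names allelic differences in expression as one of its measurements, so the comparison within each library was 129 against cas. Ratios are given as log2(129/cas) of recovered reads scaled to CPM, plus 0.1, where a positive value is higher from 129, and the 129 share of a gene's reads is given as mean ± SD over the libraries (n = 2). Nothing in the labels says that the libraries came from separate cultures, so the spread between them may be technical. The SEs and p-values of single genes rest on that spread pooled over genes of like abundance. A gene's SE therefore does not show how far its own libraries differed.

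Differences between the reads assigned to the alleles were widespread. Of the 15509 tested genes, 6809 (43.9%) differed between the alleles at an adjusted p under 0.05 in limma, 3402 higher from 129 and 3407 higher from cas. The difference was at least 2-fold for 2682 genes, 1648 of them higher from 129 and 1034 higher from cas, and at least 8-fold for 535 genes, 357 from 129 and 178 from cas. The median size of the log2 ratio among called genes was 0.77, against a median standard error (SE) of 0.21 over all tested genes. The direction was the same in both libraries for 6797 called genes (99.8%), which is no independent check, since the calls rest on the same libraries. Across genes, the ratios of the libraries had a Pearson r of 0.82 and a Spearman rho of 0.73, which rose to 0.91 and 0.81 among genes with at least 100 reads in each library; genes are not independent replicates, so no p is attached. The even split of directions depended on scaling each allele column to the typical gene. With 1 shared library size for both alleles, the median of all genes moved to 0.32 and 81.3% of 7997 calls were higher from 129; with the deposited column totals the median was 0.10 and 61.9% of 6767 calls were higher from 129. An exact binomial test in each library against its overall 129 share, which differs in the test as well as the scaling, made 7031 calls, 61.0% of them higher from 129. Requiring a change beyond 1.5-fold left 1982 calls, 59.9% of them higher from 129, and leaving out the pairing of alleles by library (no block) left 3954. All ratios below are relative to the typical gene. A call shows a difference in assigned reads that repeats between the libraries, whatever its source. A preference in read assignment that differs between genes was not tested. RNA of the fibroblasts in the feeder layer was not separated from that of the ES cells.

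Among genes with at least 100 reads in each library, and leaving out genes with symbols of predicted genes, small RNAs of the Mir and Snor types and -ps pseudogenes, the genes with the largest ratios toward 129 included extracellular matrix genes. Tm4sf1, a membrane protein of the tetraspanin-like family (chromosome 3, 57285611 to 57301988, mm10), had 99.7% ± 0.16 of its reads from 129, with a log2 ratio of 7.68 (SE 0.38, adjusted p = 1.7e-86). Biglycan (Bgn), tenascin C (Tnc) and collagen III (Col3a1) had only 1 to 3 cas reads over both libraries. Their pooled 129 shares were 99.9% (exact 95% interval 99.3 to 100.0), 99.6% (98.8 to 99.9) and 99.7% (98.4 to 100.0). Scarna17, a small Cajal body RNA, and Nupr1, a stress-induced chromatin protein, likewise had 1 and 2 cas reads, with pooled shares of 99.8% (98.7 to 100.0) and 99.5% (98.3 to 99.9). Rps3a2, annotated as a processed pseudogene under a symbol that was not left out, and the histone gene Hist1h2bh had 0 cas reads in both libraries, so their log2 ratios were at least 6.63 and 6.44 with a floor of 3 reads over both libraries. Dnah7b, an axonemal dynein heavy chain, had 46437 and 46627 reads from 129 against 242 and 219 from cas (log2 ratio 7.32, SE 0.07). Lars2, the mitochondrial leucyl-tRNA synthetase, reached 6.71 (SE 0.03) and alone took 1.94% of all reads, against 0.65% for Malat1. Whether the reads counted for Dnah7b and Lars2 are transcripts of those genes was not tested.

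Toward cas, the largest ratio under the same rule for symbols belonged to Il1rapl1, a synaptic receptor-like protein (chromosome X, 86740870 to 88115645), with 0.25% ± 0.11 of its reads from 129 and a log2 ratio of -9.03 (SE 0.06). The spliceosomal RNA gene Rnu5g had a ratio of -7.64 (SE 0.20), from -8.29 in library 1 and -7.00 in library 2, and the cation channel gene Trpm3 one of -6.42 (SE 0.04). Fgfr2, a fibroblast growth factor receptor, had a ratio of -6.52 (SE 0.04), but its annotated span of 130162451 to 133123350 on chromosome 7 overlaps 36 other genes on the same strand. Hist1h1d, a linker histone, had -6.27 (SE 0.46), Tuba3b, an alpha tubulin, -5.28 (SE 0.58), the granulocyte growth factor receptor Csf3r -4.49 (SE 0.54) and Frmd3 -4.49 (SE 0.33). The 5.8S ribosomal RNA copy n-R5-8s1 and Gfer, a mitochondrial sulfhydryl oxidase, had 1 and 3 reads from 129 and pooled 129 shares of 0.33% (exact 95% interval 0.01 to 1.85) and 0.77% (0.16 to 2.24). Intervals cover counting error only. Trpm3, Fgfr2 and Il1rapl1 were among the genes with the most reads, with 0.63%, 0.60% and 0.31% of all reads. Whether these reads are transcripts of the genes themselves was not tested. Pseudogenes, histone genes and small RNA genes have near-identical copies elsewhere in the genome, and how the counting treated such reads is not given in the sources used here, so their ratios are uncertain.

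Genes of the imprinted lists are known for expression from 1 parent's chromosome, which need not hold in every tissue. Whether each is imprinted in these ES cells was not tested, and the labels do not say which strain was the mother. In the Dlk1-Meg3 domain of chromosome 12, the maternally expressed noncoding RNAs Meg3, Rian and Mirg gave most of their reads from cas, with 129 shares of 22.9% ± 1.49, 22.4% ± 0.69 and 21.8% ± 0.16 and log2 ratios of -2.08 (SE 0.07), -2.12 (SE 0.05) and -2.17 (SE 0.09). The paternally expressed Dlk1, a Notch-related ligand gene in the same domain (109452823 to 109463336), gave 95.5% ± 0.72 from 129, a log2 ratio of 3.84 (SE 0.50, adjusted p = 2e-13). Rtl1, a paternally expressed retrotransposon-derived gene, went the other way from Dlk1 with 21.3% ± 0.57 from 129, close to the noncoding RNAs; 6 annotated genes overlap it on the opposite strand, and whether reads were counted by strand is not given in the sources used here.

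Of the 20 tested maternally expressed genes, 3 were higher from 129 and 7 from cas, and 10 were not called; adjusted over the list alone the counts were 3 and 8. Besides the chromosome 12 genes, Asb4 gave only 8.76% ± 1.30 of its reads from 129 (log2 ratio -3.33, SE 0.68). Igf2r, the receptor that clears insulin-like growth factor 2, was higher from 129 with 69.7% ± 4.04 (0.88, SE 0.10), as were Cd81 (0.77, SE 0.12) and Osbpl5 (1.29, SE 0.24). Ppp1r9a, Trappc9 and Copg2 had small ratios of -0.24, -0.28 and -0.24, which turned positive with 1 shared library size. Ube3a, the ubiquitin ligase gene of Angelman syndrome, had a ratio of -0.20 (SE 0.09, adjusted p = 0.059) and Grb10 one of -0.25 (adjusted p = 0.16); Nap1l4 and Dhcr7 had 0.09 and 0.17, all without a call.

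Among the 21 tested paternally expressed genes, 6 were higher from 129, 9 from cas and 6 were not called (7 and 9 adjusted over the list alone). Snrpn, a splicing protein gene, gave 92.7% ± 1.45 of its reads from 129 (log2 ratio 3.25, SE 0.36). Sfmbt2, on chromosome 2, and Plagl1, on chromosome 10, gave 82.0% ± 0.82 and 82.3% ± 4.98 (1.86, SE 0.06, and 1.91, SE 0.12), and the adaptor gene Gab1 71.5% ± 0.03 (1.00, SE 0.07). Peg3 and Peg10 were higher from cas, with 34.7% ± 1.45 and 40.4% ± 1.17 from 129 (-1.24, SE 0.07, and -0.89, SE 0.10). Inpp5f (-0.68), Mest (-0.73), Zfp264 (-0.51), Impact (-0.50), Slc38a4 (-0.49) and Zdbf2 (-0.30) were also higher from cas, of which Zdbf2 turned positive with 1 shared library size. Mest had -0.47 in library 1 and -0.98 in library 2, and Zfp264 -0.18 and -0.84. Airn, antisense to Igf2r, had 0.46 (SE 0.13), from 0.16 in library 1 and 0.76 in library 2. Snhg14 (0.16), Sgce (-0.26), Nespas (-0.20) and Usp29 (-0.43) were not called.

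As sets, the imprinted lists did not stand apart in 1 direction. The median log2 ratio of the maternally expressed list was -0.22, at percentile 6.2 of 10000 random lists matched on reads (p = 0.13, permutation test over genes, two-sided). That of the paternally expressed list was -0.26 while its mean was 0.22, at percentile 2.5 (permutation test over genes, p = 0.05, adjusted p = 0.28 over the lists). Without replicate 2 the median was -0.15 and p was 0.28. With 1 shared library size the medians were 0.11 and 0.07.

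Genes typical of fibroblasts were higher from the 129 allele as a group. Of 37 tested genes in the list for the feeder layer, 29 were higher from 129 and the other 8 were not called (30 adjusted over the list alone). The median log2 ratio was 1.94, a 3.85-fold excess, with 1.68 in library 1 and 1.85 in library 2. Cd44, the hyaluronan receptor (chromosome 2, 102811141 to 102901665), gave 96.5% ± 0.95 of its reads from 129 (log2 ratio 4.48, SE 0.09), and Col5a1, a fibrillar collagen gene, 71.6% ± 1.82 (1.01, SE 0.09). The actin-binding Cald1 gave 68.1% ± 1.32 (0.76, SE 0.07), while fibronectin (Fn1), the list's most abundant member with 24172 and 25769 reads from 129, gave 58.3% ± 1.46 (0.15, SE 0.04). The list's median lay above all of 10000 random lists matched on reads, whose highest was 0.65 (adjusted p = 0.0034 over the lists), and the share of called genes was 78.4% against 43.8% elsewhere (Fisher's exact test, adjusted p = 0.00059). The strain of the feeder cells is not in the labels.

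**Figure D1:**
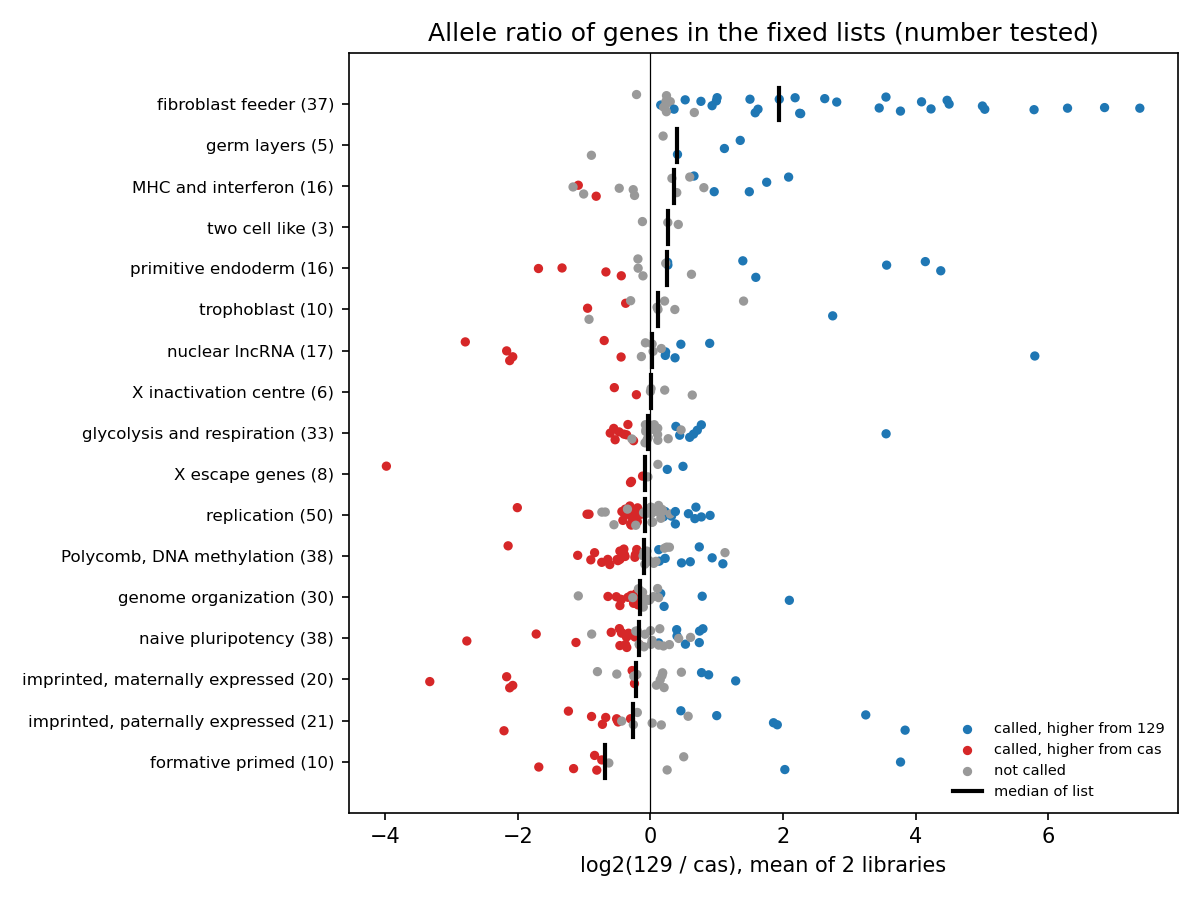
Points show log2(129/cas) of each tested gene in the fixed gene lists, as the mean of the 2 libraries, blue where called higher from 129, red where called higher from cas and grey where not called; black bars are list medians and the number tested stands in brackets. The fibroblast list has a median of 1.94, and the other list medians lie between -0.68 and 0.41.

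Called genes of the primitive endoderm and trophoblast lists went both ways, and the medians of the lists of other early lineages lay inside the range of random lists (permutation tests over genes, adjusted p = 0.425 for primitive endoderm, 0.94 for trophoblast, 0.544 for germ layers and 0.94 for the 2-cell-like state). In the primitive endoderm list, 7 of 16 tested genes were higher from 129 and 4 from cas, the same counts as adjusted over the list alone. The growth factor receptor gene Pdgfra gave 96.4% ± 0.99 from 129 (log2 ratio 4.38, SE 0.25). Whether RNA of the feeder cells added to its 129 reads was not tested. The endocytic receptor gene Cubn had a ratio of 4.15 (SE 0.35), from 3.11 in library 1 and 5.19 in library 2. The laminin gene Lama1 (-0.67, SE 0.06) and the collagen gene Col4a1 (-0.44, SE 0.07) were higher from cas, Lamc1 (0.26, SE 0.05) was higher from 129, and Lamb1 had -0.11 without a call. The list's median was 0.25, with 0.35 in library 1 and -0.04 in library 2. Of 10 trophoblast genes, 1 was higher from 129 and 2 from cas (1 and 1 adjusted over the list alone), with a median of 0.11, from -0.12 in library 1 and 0.12 in library 2. Gata2 had 2.75 (SE 0.69), Tead4 -0.37 (SE 0.08) and Eomes -0.95 (SE 0.40). Krt8 (0.10), Cdh3 (0.21) and Tfap2c (0.37) were not called. In the germ layer list, with 5 tested genes and a median of 0.41, Kdr (1.12, SE 0.44), Pax3 (1.35, SE 0.48) and Map2 (0.41, SE 0.08) were higher from 129, also when adjusted over the list alone, and Nes had 0.19 without a call. In the list of genes of the 2-cell-like state, Eif1a, Usp17la and Zscan4d were tested, with ratios of -0.12, 0.42 and 0.26 and adjusted p of 0.14, 0.64 and 0.81, and a median of 0.26, against 0.07 in each library alone.

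Of 38 tested genes of naive pluripotency, 7 were higher from 129 and 16 from cas (8 and 17 adjusted over the list alone). The median of -0.17 lay inside the range of random lists (permutation test over genes, percentile 7.0, adjusted p = 0.425 over the lists). With 1 shared library size it was 0.16. Prdm14, a regulator of germ cell and naive identity (chromosome 1, 13113457 to 13127163), gave 15.9% ± 5.80 of its reads from 129 (log2 ratio -2.77, SE 0.15), and the maternal-effect gene Dppa3 27.3% ± 7.63 (-1.72, SE 0.35). Jarid2, a Polycomb cofactor, had -0.46 (SE 0.03), and Tet1, a methylcytosine dioxygenase gene on chromosome 10, was higher from 129 with 67.7% ± 0.60 (0.74, SE 0.04). The transcription factor genes Esrrb (-0.08, SE 0.04) and Tfcp2l1 (0.00, SE 0.04) were not called. Among 10 tested genes of the formative and primed states, 5 were higher from cas and 2 from 129 (6 and 2 adjusted over the list alone). Lef1, a Wnt effector, had -1.69 (SE 0.06), the de novo methyltransferase genes Dnmt3a and Dnmt3b -0.84 (SE 0.10) and -0.73 (SE 0.12), and Etv5 -0.81 (SE 0.05). Foxd3, in contrast, had 3.77 (SE 0.52), from 4.61 in library 1 and 2.94 in library 2, and Nr2f1 had 2.03 (SE 0.84) from 0.87 in library 1 and 3.19 in library 2. The list's median of -0.68 lay at percentile 0.1 (adjusted p = 0.017 over the lists), while its mean was 0.07 and its median without replicate 1 was -0.76. Without replicate 2 it was -0.32, inside the random range of -0.39 to 0.51 (permutation test over genes, p = 0.10), so the list's call rested on library 2.

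Replication timing is one of the measurements of the series. Of 50 tested genes of DNA replication, 10 were higher from 129, 19 from cas and 21 were not called, with the same calls adjusted over the list alone. The median of -0.09 lay inside the range of random lists (permutation test over genes, p = 0.66). With 1 shared library size it was 0.24 and with the deposited column totals 0.01. Rpa3, a subunit of the single-strand binding complex, had -2.01 (SE 0.39), and Prim2, a primase subunit, 0.69 (SE 0.06). Recql4 had -0.96, from -0.38 in library 1 and -1.53 in library 2. Rif1, a regulator of replication timing, had -0.14 (SE 0.04) and Topbp1 -0.30 (SE 0.06), both turning positive with 1 shared library size; Pola1 had 0.02 without a call. Among 30 genes of genome organisation, 4 were higher from 129 and 13 from cas (4 and 14 adjusted over the list alone), with a median of -0.15. Lmna, encoding the A-type lamins, gave 84.4% ± 0.01 of its reads from 129 (2.10, SE 0.13). Whether RNA of the feeder cells added to the 129 reads of Lmna was not tested. Lmnb2, on chromosome 10, gave 68.3% ± 4.77 from 129 (0.78, SE 0.19). The cohesin loader gene Nipbl had -0.29 (SE 0.05) and turned positive with 1 shared library size, the cohesin gene Stag1 had 0.15 (SE 0.04), Mki67 0.21 (SE 0.04), and Top2a -0.01 without a call.

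In the list of Polycomb and DNA methylation genes, 8 of 38 were higher from 129 and 18 from cas (9 and 18 adjusted over the list alone). The median was -0.10, with -0.13 without replicate 1, -0.17 without replicate 2 and 0.22 with 1 shared library size. The share of called genes, 68.4%, exceeded that of other genes (Fisher's exact test, adjusted p = 0.024), but random lists matched on reads gave 55.0% on average with a 95% range of 39.5 to 71.1. Phf19 had -1.10 (SE 0.27), Kdm5b -0.40 (SE 0.04), and Mtf2 -0.05 without a call; Pcgf1 had -2.15 (SE 0.82), from -0.97 in library 1 and -3.32 in library 2. Apart from this list and the fibroblast markers, Fisher's test gave no adjusted p under 0.05. Of 17 nuclear long noncoding RNAs, 6 were higher from each allele (7 from 129 and 6 from cas adjusted over the list alone), with a median of 0.02 and a mean of -0.14. Lncenc1, an ES cell transcript (chromosome 13, 97434970 to 97497007), gave 98.6% ± 0.12 of its reads from 129 (5.80, SE 0.10). Gm26917 had -2.79 (SE 0.04), Pvt1 -0.44 (SE 0.03), Malat1 0.23 (SE 0.03) and Firre, on the X chromosome, 0.37 (SE 0.04). Gm26917 held 0.23% of all reads, and whether these are transcripts of that gene was not tested. Of 16 histocompatibility and interferon genes, 5 were higher from 129 and 2 from cas, with the same counts over the list alone and a median of 0.36. The class I gene H2-K1 gave 78.1% ± 0.35 (1.49, SE 0.20), H2-Q4 had 1.75 (SE 0.37), H2-Q10 2.09 (SE 0.69) and Tapbp 0.66 (SE 0.28). All of these lie on chromosome 17, whose tested genes had a median log2 ratio of 0.24. Whether read assignment favoured 129 at these genes was not tested. The antiviral gene Oas1a was higher from cas with -1.09 (SE 0.08), and Irf1 had 0.40 without a call. Of 33 glycolysis and respiration genes, 7 were higher from 129 and 8 from cas, also over the list alone, with a median of -0.03 and a mean of 0.12. Tpi1, triosephosphate isomerase, gave 93.5% ± 3.10 from 129 (3.56, SE 0.27) and citrate synthase (Cs), on chromosome 10, had 0.77 (SE 0.12). Gpi1 had -0.36 (SE 0.05) and Pkm -0.26 (SE 0.05), of which Pkm turned positive with 1 shared library size; Pfkp (0.06) and Hk2 (-0.03) were not called.

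The typical X-linked gene gave reads from both alleles, in a ratio close to that of the autosomes. Of 555 tested X-linked genes, 94 were higher from 129 and 125 from cas, and the median log2 ratio was -0.07, with -0.05 in library 1 and -0.09 in library 2. The median 129 share per gene was 54.5% on the X and 55.6% on the autosomes. Over all X-linked reads pooled, 48.9% came from 129, and Il1rapl1 alone held 187524 of these reads, nearly all from cas. The X median was at percentile 1.0 of random sets of autosomal genes matched on reads (permutation test over genes, p = 0.021, two-sided), yet inside the range of single autosomes, whose medians ran from -0.13 on chromosome 16 to 0.68 on chromosome 10. It turned to 0.26 with 1 shared library size and to 0.04 with the deposited column totals, where all genes moved up, and with at least 100 reads per library its p was 0.12. The share of called genes was 39.5% on the X and 44.1% on the autosomes (Fisher's exact test, p = 0.033).

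Xist, the RNA that coats an inactive X, had 0 reads in all 4 columns, while its antisense partner Tsix (chromosome X, 103431517 to 103484957) had 151 and 179 reads from 129 and 132 and 278 from cas. Tsix spans all of Xist on the opposite strand, and since the use of strand in counting is not given, the 0 does not show that the RNA was absent. The Tsix ratio was -0.55 (SE 0.22, adjusted p = 0.034), from -0.10 in library 1 and -0.99 in library 2. Among 6 tested genes of the X inactivation centre, with a median of 0.00, Tsix and Rlim were higher from cas, also adjusted over the list alone. Rlim, an Xist activator, had -0.21 (SE 0.06) and turned positive with 1 shared library size. Ftx (0.22), Jpx (0.63, SE 0.56) and Chic1 (0.01) were not called. Of 8 genes known to escape X inactivation, 2 were higher from 129 and 4 from cas, with the same counts over the list alone and a median of -0.08. Mid1 (169685199 to 170005736) gave only 7.35% ± 1.09 of its reads from 129 (-3.98, SE 0.10). Utp14a (0.49, SE 0.08, from 0.75 in library 1 and 0.23 in library 2) and Pbdc1 (0.25, SE 0.07) were higher from 129. Kdm6a (-0.12), Ddx3x (-0.30) and Eif2s3x (-0.29) were higher from cas and turned positive with 1 shared library size; Eif2s3x had -0.18 in library 1 and -0.39 in library 2. Kdm5c (-0.04) and 5530601H04Rik (0.11) were not called.

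Chromosome 10 had the highest median ratio of all chromosomes. Of its 708 tested genes, 428 were higher from 129 and 38 from cas, and 87.3% had a positive ratio. The median log2 ratio was 0.68, a 1.60-fold excess, with 0.66 in library 1 and 0.64 in library 2, and the 25th percentile of its genes was 0.29. The share of called genes was 65.8% against 43.0% on the other autosomes (Fisher's exact test, p = 1.2e-32), and the median lay above all of 10000 random gene sets matched on reads, whose highest was 0.07 (permutation test over genes, p = 0.0002, the smallest they can give). Chromosomes 4, 14, 15, 16 and 17 reached the same p in that two-sided permutation test, so the p does not set chromosome 10 apart. By median, chromosome 17 followed with 0.24 and 220 calls for 129 against 81 for cas. The medians of the remaining autosomes ran from -0.13 on chromosome 16 and -0.12 on chromosome 14 to 0.10 on chromosome 3. This per-chromosome survey of the autosomes was planned only as the background for the X chromosome.

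**Figure D2:**
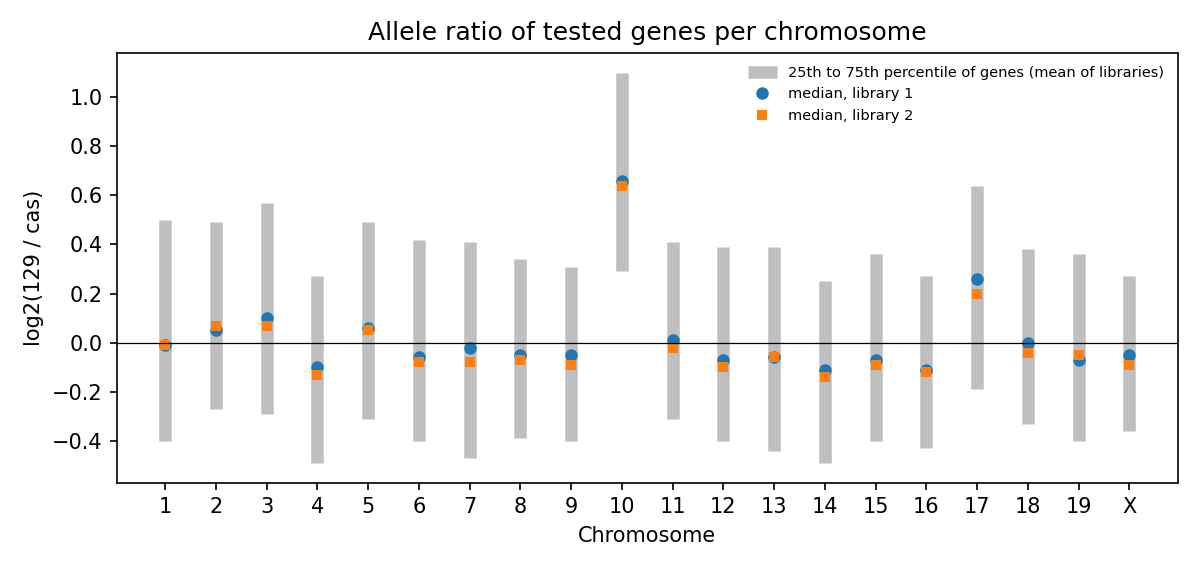
Median log2(129/cas) of tested genes on each chromosome, for library 1 (circles) and library 2 (squares); grey bars span the 25th to 75th percentile of genes for the mean of the libraries. Chromosome 10 lies at 0.66 and 0.64, above the other chromosomes, and the X at -0.05 and -0.09.

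**Figure D3:**
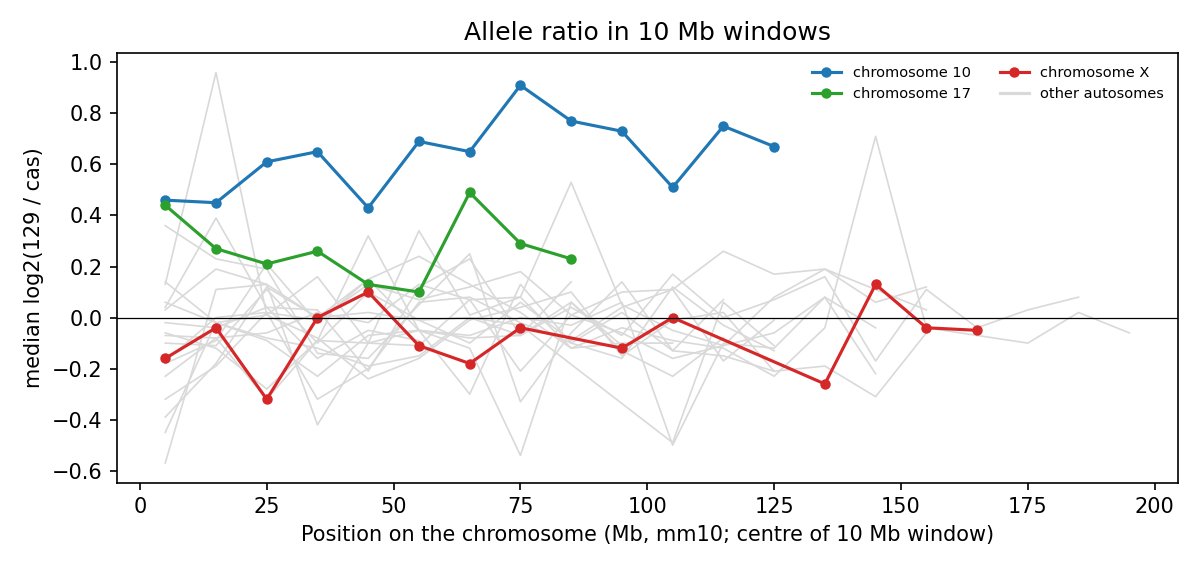
Median log2(129/cas) in 10 Mb windows with at least 10 tested genes, by position in mm10; coloured lines are chromosomes 10, 17 and X and grey lines are the other autosomes. All 13 windows of chromosome 10 lie between 0.43 and 0.91; of 250 windows elsewhere, 5 lie above 0.43, and the highest, on chromosome 5, reaches 0.96.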

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

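Reads were assigned to genes listed on the Y chromosome, which was outside the comparisons because the cells are female by the labels. Nearly all of these reads were of Erdr1, with 94426 over both libraries. Of the Erdr1 reads, 24622 and 21750 were from 129 and 25702 and 22352 from cas. They were split almost evenly in each library. A Y chromosome would carry only the allele of its own strain, so it could not give all of these reads. The split does not exclude that a Y chromosome gave part of them, so the Erdr1 reads do not show whether the cells carry one. Whether they came from a copy elsewhere in the genome was not tested. The other Y chromosome genes together had 221 reads over 23 genes, of which Gm21857 had 120 and Gm8446 had 35. Usp9y had 18 reads, Kdm5d and Uty had 6 each, and Ddx3y and Eif2s3y had 0 reads. These single genes were picked after their values were seen.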

How the results depend on the processing

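The settings for pseudocount, voom weights, deposited column totals, treat, protein-coding genes and chromosomes left out were chosen after the data were seen. The count of 6809 called genes stayed within 1.5 times under all but 2 of the alternatives run. With no replicate block it was 3954 (2150 higher from 129 and 1804 from cas), and against 1.5-fold with treat it was 1982 (1188 and 794), which by construction asks for a larger change. With 1 shared library size for both alleles, 6505 genes were higher from 129 and 1492 from cas; by construction this setting leaves the genome-wide excess of 129 reads in each ratio. It also turned the median of the maternally expressed list, past the threshold in neither setting, to 0.11, and reversed that of the paternally expressed list to 0.07, that of the X chromosome to 0.26, and the ratios of Ppp1r9a (0.09), Trappc9 (0.05), Copg2 (0.09), Zdbf2 (0.03), Rlim (0.12), Kdm6a (0.21), Ddx3x (0.03), Eif2s3x (0.04), Rif1 (0.19), Topbp1 (0.03), Nipbl (0.04) and Pkm (0.07). Other list medians that turned positive with 1 shared library size were those of naive pluripotency (0.16), replication (0.24), genome organisation (0.18), Polycomb and DNA methylation (0.22), X escape (0.25) and glycolysis and respiration (0.30). All of them stayed inside the range of random lists. The deposited column totals turned the X median to 0.04 and those of replication, X escape and glycolysis and respiration to 0.01, 0.02 and 0.07. With at least 100 reads per library the X median was -0.06 and no longer past the threshold. The paternally expressed list, not called after adjustment over the lists, lay just under the threshold before adjustment (permutation p rounding to 0.05) and above it with a minimum of 10 reads (-0.26, p = 0.063), voom weights (-0.26), a pseudocount of 0.02 (-0.26) or the deposited totals (-0.15); the cause was not tested. Leaving out each library gave medians of -0.33 to -0.15 for that list, -0.21 to -0.18 for the maternally expressed list, 1.68 to 1.85 for fibroblast markers, -0.10 to -0.08 for the other lists pooled and -0.09 to -0.05 for the X. Of single lists, 5 had medians of opposite sign in the libraries (primitive endoderm, trophoblast, nuclear noncoding RNAs, X inactivation centre, and glycolysis and respiration), none of them called. The formative and primed list lost its call without replicate 2 (-0.32, against -0.76 without replicate 1) and kept it in its other alternatives. The fibroblast median stayed between 1.68 and 2.27 in all its alternatives. Of 135 named genes, 29 lost their call with no replicate block, 50 against 1.5-fold, 9 with 1 shared library size (Mest, Zfp264, Tsix, Col4a1, Tead4, Eomes, Recql4, Kdm5b and Gpi1, all higher from cas), which added 20 calls, and 8 with the deposited totals, while no sign of a called gene changed when either library was left out. A leave-one-out count of calls was not run, because 1 library leaves no residual degrees of freedom. The count models fixed before the data were examined were not run, by choice of a log-scale test for values deposited as RPKM, although whole reads were recovered. Of simulated 1.5-fold changes 67.2% were recovered, so smaller differences can be missed.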

Other observations

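Processed pseudogenes had the most extreme allele ratios. Of 295 tested, 132 (44.7%) differed by more than 8-fold, 65 toward 129 and 67 toward cas, against 257 of 13216 protein-coding genes (1.9%; Fisher's exact test, p = 2.1e-129). Among long intergenic noncoding RNAs the share was 51 of 561 (9.1%), and among small RNA genes 18 of 52 (34.6%). A few loci took many reads from 1 allele: Camk1d, with 8.2% and 10.5% of its reads from 129, held 1.65% of all reads, and Il31ra, with 98.9% and 97.8%, held 0.61%. These genes were picked after their values were seen.

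The tests below were chosen after the results were seen, except the test of a second fibroblast list and that of chromosome 10 genes divided by read number, whose bounds were written before those values were read.

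Fibroblast markers were higher from 129, with a median of 1.94. A preference for 129 in read assignment that is alike for all genes would not set the list apart from random lists, whose highest median was 0.65. That comparison is the pattern itself and no separate test, and a preference that differs between genes was not tested. Few of the list's members lie on chromosome 10, so leaving them out could change the median little, and it was 2.18 without them. A candidate explanation is RNA from feeder fibroblasts that carry no cas alleles. A second list of fibroblast genes had a median of 0.98, above all random lists (highest 0.55) but just under the bound of 1 set for it, with 24 of 46 genes higher from 129 (Axl 4.64, Cxcl12 4.08) and 7 from cas (Mfap5 -2.75, Igfbp3 -2.21), so feeder RNA cannot be told apart from allelic differences in the ES cells. The 4 members of the first list with the most reads, Fn1, Cd44, Cald1 and Col5a1, had 0.15, 4.48, 0.76 and 1.01; the feeder strain is not in the labels and no biological explanation was tested.

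Chromosome 10 was higher from 129, with a median of 0.68. Feeder RNA is argued against because the 25th percentile of its genes, 0.29, lay 8.5 SDs above the mean of the other chromosomes (highest -0.19), and read assignment at single loci because 100.0% of its 13 windows of 10 Mb lay above the 95th percentile of windows elsewhere (0.25). Unequal copy number of the alleles of chromosome 10, as from an extra 129 copy in some cells, may account for it. In 3 equal sets of 236 genes with low, middle and high read numbers the medians were 0.81, 0.73 and 0.57. All lay above the bound of 0.4 set for them and met a second bound on their distance from each other, but they fell as read number rose. Any shift along the whole chromosome would pass this test, so it cannot tell copy number from other such causes. No DNA measurement was used here, so unequal copy number stays a hypothesis, and a difference in transcription along the whole chromosome was not tested.

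For the pseudogenes, low read numbers are argued against, since at 100 or more reads in each library their share beyond 8-fold was still 48.3 percentage points above that of protein-coding genes. Reads shared with near-identical copies may account for it: the ratios went both ways, and small RNA genes with many copies had 44.4% beyond 8-fold at that depth. No biological explanation was tested.

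A last hypothesis was that the 129 chromosomes came from the father. Of 12 imprinted genes with a called difference of at least 2-fold, 9 went in the direction it predicts, 4 of 5 maternally expressed genes toward cas and 5 of 7 paternally expressed genes toward 129 (exact binomial test, two-sided, p = 0.15). The genes are too few, and those of 1 domain are not independent. The test also assumes even odds, whereas 1648 of the 2682 called genes with a 2-fold difference were higher from 129. Plagl1, counted toward 129, lies on chromosome 10, which was itself higher from 129. Rtl1, counted toward cas, is overlapped by 6 genes on the opposite strand, and the use of strand in counting is not given. Feeder RNA without cas alleles would move any gene it contains toward 129, whichever parent the chromosome came from, and was not separated here. The parent of each chromosome set may therefore be either and stays open.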
